A study of Mus musculus with 4 samples.

How the data were processed

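Aortic RNA of 4 groups of mice was analysed, C57BL/6 and C3H/HeJ mice without apolipoprotein E on chow or Western diet, with 1 array per group. Per the labels' protocols, animals were weaned at 3 weeks, the diet was switched at 4 weeks, total RNA was extracted with Trizol, and 8 ug was turned into biotin-labelled cRNA for a 1-colour Affymetrix array. The deposited values are linear intensities of 22690 probe sets, 64 of them controls, which were left out. The software and background step behind these intensities are not given in the sources used here. The deposited arrays share 1 mean after trimming 2% at each end (250.11 to 250.12), so they had been put on a common scale, while their medians ranged from 110.3 to 128.1, a ratio of 1.16.

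The design fixed before the data were examined kept the deposited values if medians and trimmed means lay within 10% of each other and otherwise asked for quantile normalization. Read between pairs of arrays the medians exceeded this limit, so values were quantile normalized on the log2 scale. Read against the mean of the medians, all arrays lay within the limit, and the deposited values would have been kept. They were therefore run as an added alternative. No detection calls accompany the values. A floor was set at the 40th percentile of all values (signal 83.6), a threshold of this work and not of the array maker, and a value at or under it is taken as a bound. A fold against such a value is given as "at least", with the dim array raised to the floor.

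Gene names came from the platform's annotation. Of 22626 probe sets, 20380 name 1 gene, 691 name several and 1555 are unnamed here, for 12393 genes. Entrez identifiers of 20351 probe sets matched the RefSeq gene table of assembly GRCm38.p6, which was used for names only and updated 0 symbols. A gene is represented by its probe set with the highest mean log2 signal, and its further probe sets are given in the text where they differ most from it.

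Differences within a pair of arrays were counted at 2-fold where both arrays were above the floor, with no test, since neither side has a replicate. Counts shared by both pairs were set beside n1 x n2 / N of independent lists. The paired comparisons share no array. An additive fit in limma 3.58.1 (R 4.3.3) with terms for strain and diet, eBayes with a mean trend and Benjamini-Hochberg adjustment at 0.05 was run on 14915 probe sets above the floor on at least 2 arrays. Signals under the floor entered this fit as measured values. Its only residual is the unreplicated interaction, so the fit assumes that diet acts alike in both strains apart from noise. Its p-values rest mostly on a variance shared across probe sets of similar signal (prior of 17.3 degrees of freedom against 1 residual). That variance comes from the spread between arrays, which can be technical, and not from replicates of a group. An exact test of 2 arrays against 2 cannot go below p = 0.333 two-sided. The strain term was tested on simulated data with independent noise of SD 0.666 (log2) for every probe set. It recovered 3.0% of 2-fold, 17.9% of 4-fold and 81.8% of 8-fold changes among 14915 probe sets, with 1 false call. That noise had no mean trend and no strain-by-diet interaction, so these rates do not describe the error of the calls below.

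The 23 gene lists, for pathways, for cell types of the aorta and the tissue around it, for the MHC locus and, with the immediate early and stress response list, for tissue and RNA handling, were fixed before the data were examined. For each list the median log2 difference is given with its percentile among 10000 random lists of the same size matched on mean expression, which describes these arrays and is not a test. Genes were named by a fixed rule. It takes up to 10 genes per direction that differ at least 2-fold between strains on both diets, up to 6 per direction by bound, up to 8 per direction shared in their diet response, up to 6 per direction with the largest response in each strain and the largest difference of responses, the fixed single genes, and up to 4 members per list. A list of heart muscle genes was drawn up after the values were seen. Alternatives were the deposited values, equal array medians, cyclic loess, floors at the 25th and 60th percentile, 1 probe set per gene, thresholds of 1.5-fold and 3-fold, no filter, and limma without a mean trend. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest.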

Results

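Gene expression was measured in the aorta of female mice that lack apolipoprotein E, a protein needed to clear lipoprotein remnants from blood, at 6 weeks of age. The defect was carried on the C57BL/6 or the C3H/HeJ background (C3H below), and each strain ate chow throughout or a Western diet for the last 2 weeks. Apolipoprotein E-deficient C57BL/6 mice are known to form large atherosclerotic lesions and C3H/HeJ mice small ones, so the comparisons ask how the aorta differs between the strains and how it responds to diet in each. Each of the 4 groups had 1 array, and whether its RNA came from 1 animal or from a pool is not given in the sources used here. No group therefore has a replicate, and the number of arrays limits the precision of every value below.

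Of 22626 probe sets, 18923 were above the floor signal of 83.6 on at least 1 array and 8740 on all 4. Apoe itself lay under the floor on every array (19.1 and 65.3 on C57BL/6 chow and Western, 16.1 and 55.5 on C3H chow and Western). It has 1 probe set, whose place relative to the disrupted part of the gene is unknown here, and no wild type was analysed here, so this checks the labels little. Xist, expressed in females, gave signals of 364 to 952, and the Y-linked Eif2s3y gave 3.39 to 8.19, although the Y-linked Kdm5d reached 96.3 and 102 on the chow arrays. The C3H chow array stood apart in several quality measures. Its hybridization controls were 1.71-fold higher (median of 9 probe sets), its actin 3'/5' signal ratio was 2.28 against 1.63 to 1.83 on the other arrays, and its correlations with them were 0.868 to 0.904, where the other pairs reached 0.913 to 0.931. Its Gapdh 3'/5' ratio of 1.19 lay within those of the other arrays (1.03 to 1.28).

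Among the largest strain differences were transcripts of heart muscle, a group picked out after the values were seen, which were abundant on both C57BL/6 arrays and far lower on both C3H arrays. Myl7, the atrial myosin light chain, was at least 34.4-fold lower in C3H on chow and at least 26.5-fold lower on Western diet, from C57BL/6 signals of 2876 and 2216. Tnnt2 and Tnni3, subunits of cardiac troponin, were at least 24-fold and 16.8-fold lower on chow and at least 15.5-fold and 12.5-fold lower on Western diet. Myoglobin (Mb), measured on all 4 arrays, was 5.69-fold lower on chow and 8.82-fold lower on Western diet, and phospholamban (Pln), a regulator of the cardiac calcium pump, was 5.67-fold and 5.0-fold lower. Some stayed well above the floor in C3H on chow and Western diet, with signals of 452.8 and 210.7 for Mb and of 2336 and 2003 for the calcium pump gene Atp2a2. Actc1, cardiac actin, had signals of 4417 and 3428 in C57BL/6 against 111.5 and 50.7 in C3H, with adjusted p = 8.08e-08 in limma. The 50.7 lies under the floor, and limma took it as measured. The fitted strain difference was log2 -5.69, against -5.33 with that signal raised to the floor. Of the fixed skeletal and cardiac muscle list, 11 members were measured in both chow arrays, with a median log2 difference of -0.94 (6 at least 1.5-fold lower and 3 higher, and -2.50 with the floor at the 60th percentile), and 10 in both Western arrays, with a median of -0.94 (5 lower and 2 higher). Of its skeletal muscle members, Casq1 (log2 -0.23 and 0.88) and Atp2a1 (0.38 and 0.97) were not lower on both diets, and Acta1 was lower on chow only (-1.89 and 0.18). Fast skeletal muscle genes, 10 members grouped after the values were seen, stood highest on C57BL/6 chow. Their median log2 signal relative to the mean of the 4 arrays was 0.81 there. It was -0.58 on C57BL/6 Western, -0.09 on C3H chow and 0.24 on C3H Western.

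**Figure D1:**
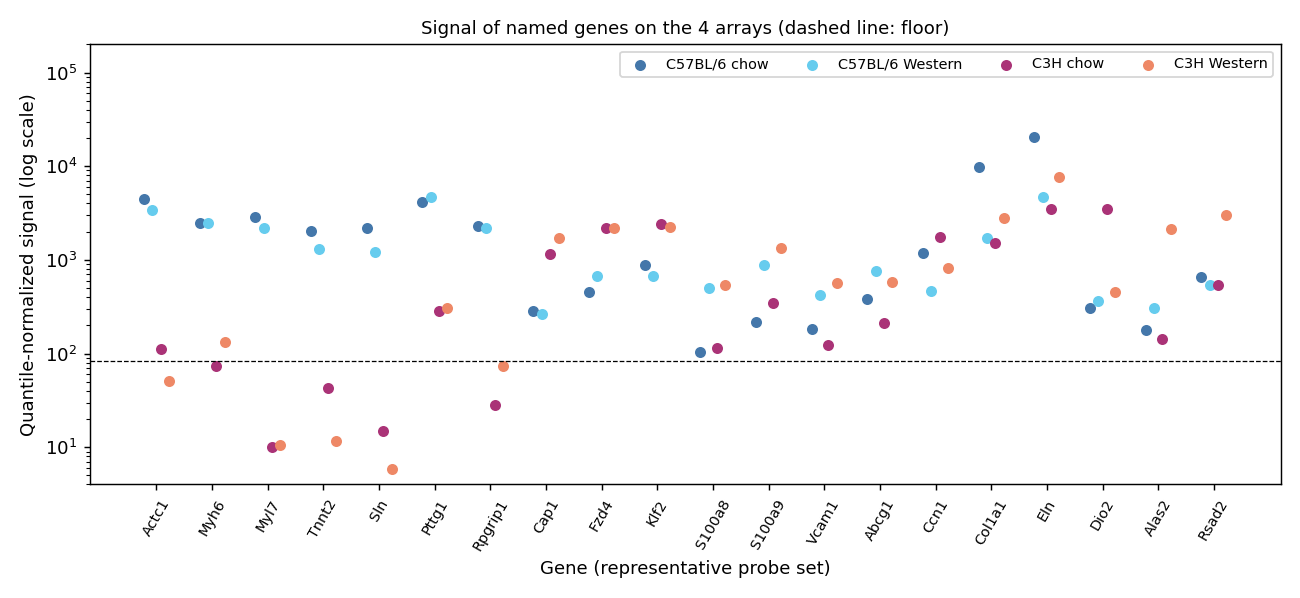
Quantile-normalized signal (log scale) of 20 named genes on the 4 arrays, with each point 1 array and the dashed line the floor signal of 83.6. Actc1 lies at 4417 and 3428 on the C57BL/6 arrays and at 111.5 and 50.7 on the C3H arrays, while S100a8 lies at 496.3 and 538.0 on the Western arrays and at 104.3 and 115.6 on the chow arrays.

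Outside heart muscle, Pttg1, which encodes securin of the cell cycle, was 14.3-fold lower in C3H on chow and 15.4-fold lower on Western diet (limma adjusted p = 9.58e-07), and its further probe set differed by log2 -2.89 (further sets here are means over both diets, with signals under the floor raised to it). Inmt, a methyltransferase, was 4.62-fold and 4.26-fold lower. Rpgrip1 was at least 27.8-fold and 26.4-fold lower by 1 probe set, while its other probe set differed by log2 0.11. Higher in C3H were Cap1, an actin regulator, by 4.02-fold on chow and 6.50-fold on Western diet (limma adjusted p = 0.00158, and log2 2.42 by its further probe set), and Alad, an enzyme of heme synthesis, by 4.66-fold and 3.76-fold. The growth factor Hbegf was 5.16-fold and 3.78-fold higher by 1 probe set, while its other set differed by log2 -0.28 on chow and had a C57BL/6 signal of 11.6, under the floor, on Western diet. Gbp2b, an interferon-induced GTPase, was at least 3.44-fold and 4.73-fold higher but had a limma adjusted p of 0.45. Fzd4, a Wnt receptor, was 4.84-fold and 3.29-fold higher by 1 probe set, and its other probe set differed by log2 -0.54.

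Genes of the major histocompatibility complex, which differ in sequence between the strains (haplotype b in C57BL/6, k in C3H), were mostly lower in C3H. The MHC list had a median log2 difference of -0.89 on chow (7 of 8 measured members at least 1.5-fold lower, percentile 0.22 among random lists) and -0.48 on Western diet (4 of 10 members, percentile 0.27). That median on Western diet was -0.14 when all probe sets of each member were used. H2-K1 was 16.5-fold and 10.4-fold lower by its representative probe set, while its further sets ranged from log2 -2.92 to 0.81. Probe sets of H2-D1 pointed in opposite directions, with 1 higher by at least log2 4.25 in C3H and others reaching -3.82. Immediate early and stress response genes, a list fixed as a sign of tissue and RNA handling, were higher in C3H, with medians of 0.69 on chow (13 of 23 members at least 1.5-fold higher and 3 lower, percentile 99.97) and 0.82 on Western diet (14 of 23 higher and 3 lower, percentile 100). Fos was 2.86-fold lower in C3H on chow and 2.56-fold higher on Western diet. Among the others the flow-responsive Klf2 was 2.76-fold and 3.35-fold higher (limma adjusted p = 0.0181), Nr4a1 was 3.25-fold and 2.60-fold higher (limma adjusted p = 0.0246), and Atf3 was 4.35-fold and 3.07-fold higher with a limma adjusted p of 0.215.

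Across probe sets, 863 were at least 2-fold higher and 941 lower in C3H on chow (of 10522 measured), and 457 were higher and 464 lower on Western diet (of 10956). Both diets gave 58 higher, 81 lower and 47 in opposite directions among 8740 probe sets, where independent lists of the same sizes would share 27.9, 36.9 and 64.3. The differences on the 2 diets correlated with Pearson r = 0.118 and Spearman rho = 0.077 across probe sets, which are not independent replicates. The additive limma fit takes the strain-by-diet interaction as its error, with 1 residual degree of freedom beside the prior of 17.3. In this fit, 57 of 14915 probe sets passed an adjusted p of 0.05 for strain (18 higher and 39 lower in C3H, and 873 at an unadjusted p under 0.05). None of the 57 passed in limma when the variance prior had no mean trend (lowest adjusted p 0.63, 804 at an unadjusted p under 0.05), and 27 passed with 1 probe set per gene. Of the 57 calls, 53 name a single gene, for 46 genes, 32 lower and 14 higher in C3H, of which 16 were heart muscle genes.

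**Figure D2:**
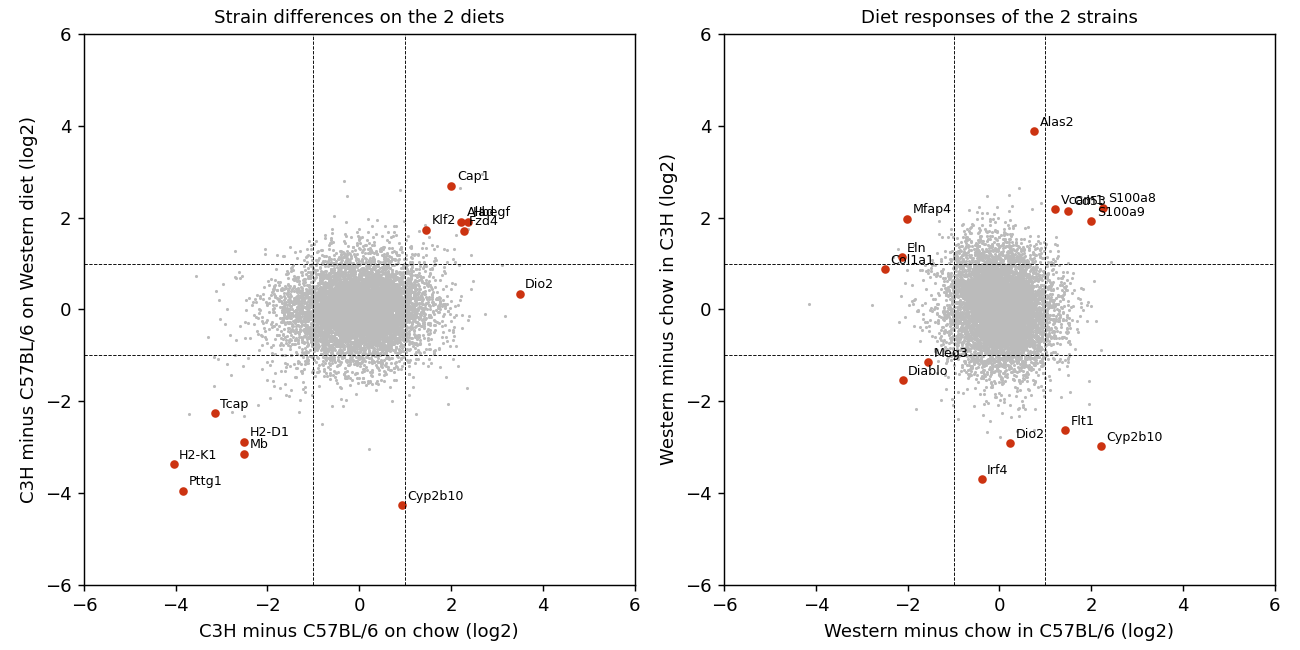
Log2 differences of 8028 probe sets that name 1 gene and lie above the floor on all 4 arrays, with each point 1 probe set, dashed lines at 2-fold and named genes in red. On the left, C3H minus C57BL/6 on chow is set against the same on Western diet, and Pttg1 lies 14.3-fold and 15.4-fold below. On the right, the Western minus chow response of C57BL/6 is set against that of C3H, and S100a8 lies 4.76-fold and 4.66-fold above.

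The genes below are among those that differed at least 2-fold with Western diet in both strains, and none passed limma. Some lay little above the floor of 83.6 on C57BL/6 and C3H chow, with signals of 104.3 and 115.6 for S100a8 and 103.7 and 103.2 for Cd53, so their folds are less certain. Others were clearer of it, with 217.8 and 350.5 for S100a9 and 297.4 and 408 for Cp. S100a8 and S100a9, which form calprotectin of neutrophils and monocytes, were 4.76-fold and 4.00-fold higher in C57BL/6 and 4.66-fold and 3.78-fold higher in C3H. The leukocyte surface protein Cd53 was 2.81-fold and 4.45-fold higher, and the endothelial adhesion molecule Vcam1 was 2.32-fold and 4.57-fold higher, with log2 differences over its 2 probe sets of 0.49 to 1.21 and 1.29 to 2.19. Ceruloplasmin (Cp) was 2.32-fold and 2.69-fold higher, although its 5 probe sets ranged from log2 0.33 to 1.22 in C57BL/6 and from -0.19 to 1.43 in C3H. The semaphorin gene Sema4b was 2.14-fold and 2.44-fold higher by 1 probe set, while its other set gave log2 -0.14 in C57BL/6 and lay under the floor on C3H Western. Nme1 was 5.37-fold and 2.05-fold higher by 1 probe set, while log2 differences by its other set were 0.42 and -0.34. Lower with Western diet in both strains were the transcription factor gene Junb (2.17-fold and 2.75-fold) and the matrix protein gene Ccn1 (2.52-fold and 2.16-fold, and log2 -1.31 and -0.63 by its other set). Both belong to the immediate early and stress response list, which was fixed as a sign of tissue and RNA handling. The noncoding RNA Meg3 was 2.93-fold and 2.21-fold lower, with log2 differences over the 3 probe sets above the floor on all arrays of -1.55 to -0.75 and -1.14 to -0.08. Diablo, a mitochondrial regulator of apoptosis, was 4.33-fold and 2.90-fold lower by 1 probe set, while its other set went the opposite way, from signals under the floor on chow (6.73 and 20.1) to 177.5 and 145.7 on Western diet.

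Among the fixed lists, sterol efflux and LXR targets, the genes switched on by oxysterols, had a median log2 response of 0.50 in C57BL/6 (4 of 11 members at least 1.5-fold higher and 0 lower, percentile 99.63) and 0.36 in C3H (4 of 12 higher and 2 lower, percentile 96.43). The cholesterol exporter Abcg1 was 2.02-fold and 2.69-fold higher. Macrophage markers had medians of 0.30 (6 of 18 higher and 0 lower, percentile 96.82) and 0.29 (8 of 19 higher and 1 lower, percentile 96.33), with the protease Ctss 1.56-fold and 2.80-fold higher. Interferon response genes had medians of 0.39 (5 of 14 higher and 3 lower, percentile 98.40) and 0.46 (6 of 18 higher and 0 lower, percentile 99.44). Between the strains the interferon list was higher in C3H on Western diet by a median of 0.57 (8 of 16 higher and 0 lower, percentile 99.97), against 0.05 on chow. Members were selected by signal separately on each diet. Over the 12 interferon members measured on all 4 arrays, the C3H diet response minus the C57BL/6 one had a median of 0.07. Of these 12, 6 were above 0 (percentile 62.35). The interferon member Rsad2 was 5.56-fold higher with Western diet in C3H and 1.22-fold lower in C57BL/6, and its 3 probe sets ranged from log2 0.25 to 2.48 in C3H. The immediate early list of the handling check had medians of -0.50 in C57BL/6 (11 of 23 at least 1.5-fold lower and 2 higher, percentile 0.00) and -0.39 in C3H (12 of 24 lower and 3 higher, percentile 0.22).

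No probe set passed the additive limma fit for diet (0 of 14915, with 367 at an unadjusted p under 0.05 and the lowest adjusted p, 0.424, at S100a9), and limma without a mean trend also gave 0 (629 at an unadjusted p under 0.05). At 2-fold, 414 probe sets were higher and 433 lower in C57BL/6 (of 10914), and 684 were higher and 635 lower in C3H (of 10681). With equal array medians in place of quantile normalization these splits were 544 and 397 in C57BL/6 and 865 and 455 in C3H, and the median of all measured probe sets in C3H moved to log2 0.11. Both strains shared 23 higher and 19 lower probe sets (36 and 12 with equal medians), while 57 went in opposite directions. Independent lists would share 22.9, 17.6 and 40.2, so the 23 and 19 lay near the counts of unrelated lists and the 57 above theirs. Across 8740 probe sets the responses of the strains correlated with Pearson r = -0.102 and Spearman rho = -0.114.

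Matrix genes were lower with Western diet in C57BL/6 and higher in C3H. The extracellular matrix and fibroblast list had a median log2 response of -1.03 in C57BL/6 (21 of 30 members at least 1.5-fold lower and 0 higher, percentile 0.00) and 0.82 in C3H (20 of 28 higher and 0 lower, percentile 100). Col1a1, a chain of type I collagen, was 5.65-fold lower in C57BL/6 and 1.84-fold higher in C3H, elastin (Eln) was 4.39-fold lower and 2.21-fold higher (log2 -4.16 and 0.13 by its other probe set), and the microfibril gene Mfap5 was 4.23-fold lower and 2.25-fold higher. Contractile genes of smooth muscle had medians of -0.42 (6 of 18 lower and 1 higher) and 0.45 (6 of 18 higher and 1 lower). Relative to the mean of the 4 arrays, the matrix list stood at 0.81 on C57BL/6 chow, -0.31 on C57BL/6 Western, -0.86 on C3H chow and 0.13 on C3H Western. The chow arrays were thus the highest and the lowest, and on chow the list was lower in C3H by a median of log2 -1.56, against 0.31 on Western diet. Contractile genes were lower in C3H on chow too, by a median of -0.92 (14 of 18 lower and 0 higher, percentile 0.00). The C3H chow array, lowest here, is the one that stood apart in several quality measures, and every C3H response is taken against it.

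Fat genes had the opposite pattern, with the brown adipocyte list highest (0.66) on that same C3H chow array. Brown adipocyte markers had a median response of 0.43 in C57BL/6 (5 of 12 members at least 1.5-fold higher and 0 lower, percentile 99.67) and -0.48 in C3H (6 of 13 lower and 0 higher, percentile 0.18). General adipocyte markers had medians of 0.38 and -0.44, fatty acid oxidation genes 0.52 and -0.34, and oxidative phosphorylation genes 0.24 and -0.32. On chow these 4 lists were higher in C3H than in C57BL/6, by medians of 1.28, 0.80, 0.55 and 0.45. With equal array medians the responses of C57BL/6 in the last 3 of them were 0.64, 0.72 and 0.44. Dio2, which activates thyroid hormone in brown fat, had a signal of 3451 on C3H chow and of 305.8 to 457.1 on the other arrays, and Ucp1, the uncoupling protein of brown fat, was 2.47-fold lower with Western diet in C3H and 1.17-fold lower in C57BL/6. Responses differed at least 2-fold between the strains for 1173 of 8740 probe sets (609 with the higher response in C3H and 564 with the lower). This difference was not tested, since 4 arrays leave no residual for it.

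**Figure D3:**
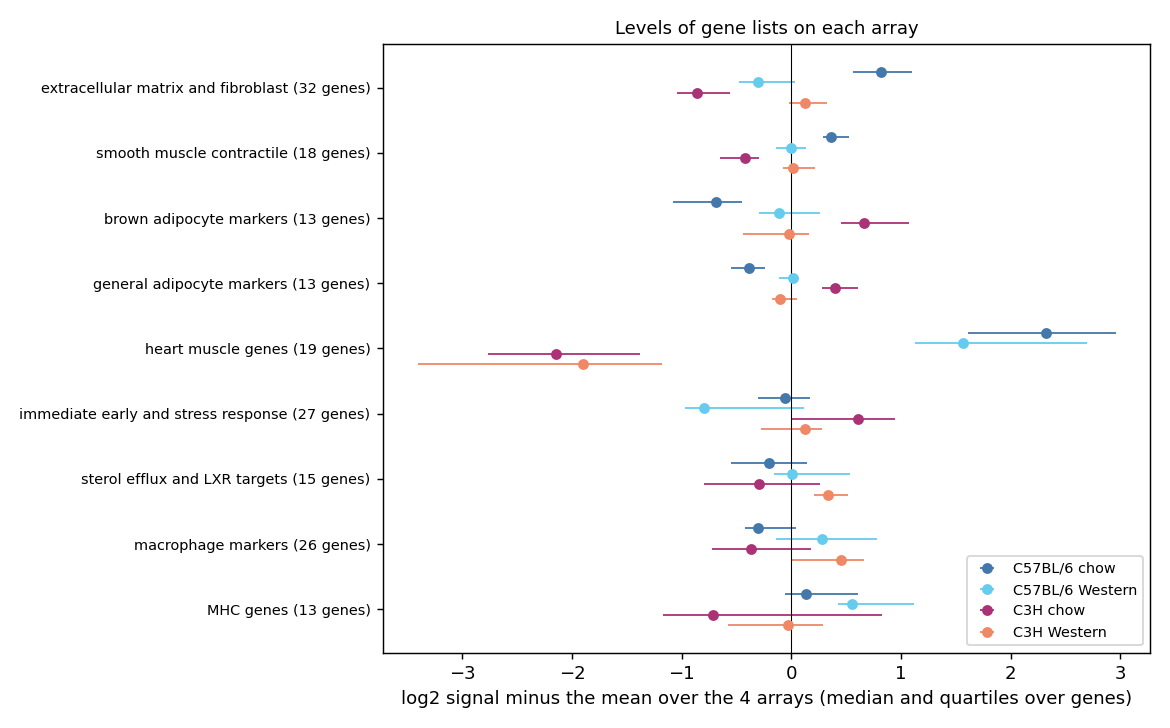
Median and quartiles over genes of log2 signal minus the mean over the 4 arrays, for 9 gene lists on each array. The matrix list lies at 0.81 on C57BL/6 chow and -0.86 on C3H chow with the Western arrays between them, the brown adipocyte list lies at -0.68 on C57BL/6 chow and 0.66 on C3H chow, and the heart muscle genes, listed after the data were seen, lie at 2.32 and 1.56 on the C57BL/6 arrays and -2.15 and -1.90 on the C3H arrays.

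Further large responses differed in size between the strains, with no test of the difference. In C57BL/6 the peroxisome proliferator receptor gene Ppara was 4.27-fold higher with Western diet (1.20-fold lower in C3H), and the lipolysis inhibitor gene G0s2 was 4.16-fold higher (1.54-fold higher in C3H). Fos, a member of the immediate early list of the handling check, was 6.89-fold lower in C57BL/6 (1.06-fold higher in C3H). In C3H the erythroid heme synthesis gene Alas2 was 14.8-fold higher (1.68-fold higher in C57BL/6) and Irf4 was 13-fold lower (1.31-fold lower in C57BL/6) by 1 probe set, while its other set gave log2 -1.43, with C3H Western under the floor. For scale, different probe sets of the same gene differed within a single comparison by a pooled SD of log2 0.602 and 0.508 for strain on chow and Western diet and 0.483 and 0.567 for diet in C57BL/6 and C3H (1675 genes). All probe sets of these genes had SDs of 0.771, 0.561, 0.555 and 0.658, so much of the variation between arrays was of the size of the disagreement between probe sets.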

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

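Of the tests in this part, the one on normalization was planned, and those on the share of vessel wall were chosen only after the result was seen. For vessel wall, 4 contrasts and a signal limit of 10000 were tried after their values were known, and all 8 intervals are counted here. Intervals come from resampling genes 10000 times, and genes are not independent replicates.

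Diet responses that pointed in opposite directions in the strains, each from 1 array per group and not tested for their difference, drew attention to 6 lists. As the C3H response minus the C57BL/6 response in log2, the median was 1.955 for extracellular matrix and fibroblast genes, 0.992 for smooth muscle contractile genes, -1.846 for brown adipocyte markers, -1.073 for general adipocyte markers, -0.827 for fatty acid oxidation genes and -0.495 for oxidative phosphorylation genes. Of the 12 genes named for the largest differences of response, 9 responded at least 2-fold in opposite directions, while Col1a1 (3.378), Slc12a2 (-3.374) and Irf4 (-3.319) stayed under 2-fold in 1 strain. The difference was 3.990 for Mfap4, 3.401 for Sfrp2, 3.289 for Col5a2, 3.279 for Eln and 3.253 for Mfap5, all genes of the matrix or secreted into it. It was -5.195 for Cyp2b10, -4.070 for Flt1, -4.009 for B3gat3 and -3.249 for Fkbp5. Further probe sets gave 4.288 for Eln, -3.504 for Cyp2b10, -0.421 as the smallest difference for Flt1 and 0.292 for Fkbp5.

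For the opposite responses of matrix genes, normalization as the cause was to show as a list difference under 1 in some setting. The difference lay between 1.943 and 2.015 in 4 normalizations, so it did not depend on the choice among them. The alternatives left the median diet response of all measured probe sets between log2 -0.040 and 0.112. They could hardly have brought the difference under 1, so the test says little more. Fat genes were not part of it. A different share of vessel wall in each sample would move matrix and contractile genes by equal amounts only if the wall had a fixed make-up. That was not measured here. Between the strains on chow their medians differed by -0.628 (95% interval -1.092 to -0.164) under the signal limit and by -0.643 (-1.132 to -0.253) without it. The 2 lists thus fell by unequal amounts. These intervals resample genes of 1 array pair, which includes the C3H chow array, and cannot exclude a different share as a part or the whole of the cause. Contractile genes were also lower in C3H on chow (median -0.915, 14 of 18) and brown and general adipocyte markers higher (1.275 and 0.795). For the diet responses the share of vessel wall cannot be told apart, because 2 of 6 intervals excluded 0 and the others did not, for example -0.336 (-0.819 to 0.114) in C57BL/6 under the limit and -0.615 (-1.0 to -0.198) without it. The 13 measured brown adipocyte markers responded in C3H by -2.917 to -0.044, and a different share of brown fat, a change in its activity, an effect of strain or diet on the matrix, and the quality of the C3H chow array stay open and untested.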

How the results depend on the processing

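The deposited values, the pair-by-pair counts and the fit without muscle genes were chosen after the data were seen, and all other settings were planned. Under the deposited values, equal array medians and cyclic loess, every total of 2-fold differences stayed within 1.5 times its value, although the diet responses shared by both strains split into 36 higher and 12 lower with equal medians (23 and 19 reported), and the correlation of diet responses lay between -0.100 and -0.085. Counts followed the floor, the threshold and the number of probe sets by construction. With floors at the 25th and 60th percentile, the strain difference on both diets gave 376 and 71 probe sets (139 reported), diet in C57BL/6 2456 and 287 (847), diet in C3H 3072 and 537 (1319), diet in both strains 212 and 12 (42), and the difference of responses 2652 and 513 (1173). At 1.5-fold and 3-fold, these were 633 and 27, 3055 and 91, 3694 and 192, 379 and 3, and 3411 and 182. With 1 probe set per gene they were 90, 520, 826, 21 and 759. The chow pair alone gave 1576 strain differences and the Western pair alone 716, among probe sets above the floor on all arrays. The correlation was -0.060 and -0.175 with the lower and higher floor, and the cause was not tested. Strain calls in limma numbered 39 to 57 under the normalizations and floors, 48 without the muscle list, 27 with 1 probe set per gene, 119 with no filter and 0 without a mean trend. Diet calls in limma were 0 throughout except 5 with no filter, where probe sets above the floor on fewer than 2 arrays enter. Leaving out an array leaves 0 residual degrees of freedom, and the strain effect is then the difference of the complete pair. No paired analysis was possible because each group had 1 array and no animal links the groups, although the limma fit does compare the strains within each diet.

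Among named genes, 2 reversed under the mean over all probe sets, Sox17 between strains on Western diet (0.124 over 2 probe sets) and Mcm7 with diet in C57BL/6 (0.090 over 4 probe sets), and the cause was not tested. Of the other values for named genes, 2488 kept their side of 2-fold or of the floor, 178 dropped under either and 54 newly passed. A reversal was counted only where the reported value was at least 2-fold, so smaller values that changed sign are not counted as reversed. Of list medians, 643 stayed within the quartiles of their members as reported and 17 did not. Probe sets under the floor give bounds only, which limits low-abundance genes.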

Other observations

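All tests in this part, namely that on probe sequence in muscle genes, were chosen only after the result was seen, as were the thresholds behind them.

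Of lists not described so far, endothelial markers had a median of 0.43 between the strains on chow (8 of 17 members at least 1.5-fold higher in C3H, percentile 97.47, and 0.23 with equal array medians) and of 0.04 on Western diet (1 of 17 higher and 3 lower). Kdr, the main VEGF receptor, was 2.04-fold and 2.28-fold higher in C3H with a limma adjusted p of 0.665, while Flt1 was 3.28-fold and Sox17 2.08-fold lower on Western diet by 1 probe set each. Cell cycle genes had a median response of -0.45 over 10 members in C57BL/6 (percentile 2.38) and -0.06 over 9 in C3H (-0.14 with the deposited values). On chow they were lower in C3H by a median of -0.51 over 10 members (percentile 1.36). Over the 23 members above the floor on at least 1 array, levels relative to the mean of the 4 arrays gave another picture. They were 0.49 and -0.18 on C57BL/6 chow and Western, and 0.44 and -0.45 on C3H chow and Western. Both differences thus depended on the members taken. Mast cell and granulocyte markers had a median response of 1.14 over 4 members in C57BL/6 (percentile 100) and 0.30 over 7 in C3H (percentile 86.95), led by S100a8 and S100a9. These medians cover different members. Over the 3 measured on all 4 arrays, the C3H response minus the C57BL/6 response had a median of -0.08 (percentile 46.62). Nerve and Schwann cell markers were lower in C3H on chow by a median of -0.76 over 5 members (3 at least 1.5-fold lower and 0 higher, percentile 2.07). On Western diet the median was 0.01 over 4 members. Over the 10 members above the floor on at least 1 array, the list stood higher on C3H chow (0.50 relative to the mean of the 4 arrays) than on C57BL/6 chow (0.15). The direction on chow thus depended on the members taken. MHC genes had a median diet response of 0.62 in C3H (percentile 99.55) and 0.26 in C57BL/6 (percentile 92.99).

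The remaining lists had medians for diet in C57BL/6 and C3H, in that order, of -0.08 and 0.16 for cholesterol synthesis and uptake, 0.29 and 0.41 for lymphocyte markers, -0.16 and 0.36 for endothelial activation genes, 0.18 and 0.09 for antioxidant genes, 0.17 and 0.15 for circadian clock genes and 0.06 and 0.30 for complement and acute phase genes. Erythroid markers had a median of -0.20 in C3H over 5 members (-0.33 with the deposited values), although Alas2 was 14.8-fold higher there. Of genes named in advance for these strains, Tlr4, whose C3H/HeJ allele carries a known missense mutation, had signals of 260.3, 217.0, 39.2 and 225.2 on C57BL/6 chow, C57BL/6 Western, C3H chow and C3H Western. Glo1 was 1.68-fold and 3.53-fold higher in C3H (log2 0.55 and 1.09 by another probe set), and Hmox1 was 2.26-fold lower in C3H on Western diet, with its C3H chow signal of 17.8 under the floor.

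Heart muscle transcripts in the C57BL/6 arrays may reflect muscle carried along with the aorta. Strain sequence differences under the probes would strike genes of any tissue. In the fixed muscle list (27 on the array), 13 members had at least 2 times the floor signal on both C57BL/6 arrays. Of these 13, 11 were at least 2-fold lower on both C3H arrays, where 0.31 would be by chance (exact hypergeometric test across genes, p = 6.79e-17). The count argues against such differences as the whole cause. The p-value adds little, because the heart genes had been seen to be low before the test was chosen and genes are not independent replicates. The signal required in C57BL/6 also kept Myl2 and Myh7 out of the test. That test replaced one on further probe sets of the called heart genes, of which 6 of 9 were at least 2-fold lower with dim signals raised to the floor, short of the 3 in 4 it had asked for. Among ventricular genes, Myl2 reached 96.4 at most on the C57BL/6 arrays by its 1 probe set, Myl3 had 422.7 and 193.9 there against 25.4 and 14.3 on the C3H arrays, and Myh7 had 35.3 and 81.0, under the floor, against 163.4 and 148.6. Atrial muscle, ventricular muscle and a strain difference in expression stay open and untested, since the design ties dissection to group, with 1 sample each.

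Many strain calls rest on 1 of several probe sets. Of 21 called genes outside heart muscle with further measured sets, 14 had none that differed 2-fold the same way with dim signals raised to the floor, 7 of them lower and 7 higher in C3H. Examples are Rgs5, Tubb5, Gnb1, Fzd4 and Rpgrip1, chosen after their values were seen. Sequence differences and isoforms under these sets stay open and untested, and no probe sequence was analysed here.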
